A study of Mus musculus with 15 samples.

How the data were processed

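Bulk RNA sequencing of mouse brown adipose tissue was analysed in 15 libraries: DJ-1 knockout (KO) and flox control (WT) mice kept for 8 weeks at room temperature or at 29 °C, with 4, 4, 4 and 3 libraries for WT and KO at room temperature and WT and KO at 29 °C. Per the submitters' notes, libraries were read on a BGIseq500 as 150 bp paired ends, aligned to mm10 with STAR 2.7.10a and quantified with RSEM 1.2.28, and tested with DESeq2 (given there as 1.3.40). The deposited table holds RSEM expected counts made by the authors, 1 value per gene symbol and library, for 24030 symbols; 7.26% of its entries have decimals, and all 15 columns were matched to a sample by name. Values were rounded to whole counts. Of the symbols, 24 had been turned into dates by a spreadsheet; they stayed in the table under those names and no value is given for them. Total estimated counts ran from 23977400 to 38801000 per library.

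Genes were kept when they passed edgeR's filterByExpr by group with a minimum count of 10, which left 15083. Libraries were scaled by TMM, and 1 model with the 4 groups and 11 residual degrees of freedom was fitted with the robust quasi-likelihood method of edgeR 4.0.16 (limma 3.58.1, R 4.3.3). It gave 4 pairwise comparisons, KO against WT at each temperature and 29 °C against room temperature in each genotype, and the interaction. P-values were adjusted over all genes tested within each comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The authors' limit of a 1.5-fold change was applied as an additional count. Log2 CPM for principal components and lists used a prior count of 1. A fold against a group with no counts is a lower bound against a floor of 3 counts over the group.

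The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule names Park7 and 11 fixed genes, the 8 largest rises and 8 largest falls of each pairwise comparison among called genes with a mean of at least 1 CPM and no overlap between the groups (symbols of predicted genes left out), the 5 largest each way in the interaction without the overlap condition, and up to 4 members with the smallest p of each list. The text names 104 of the genes it gives, and some others that the rule gives are not reported here. Of 40 gene lists, 39 had tested members; they were tested with limma's camera at its preset correlation of 0.01 and again with a correlation estimated from the data, and members were also counted after adjustment over the list alone. Which libraries share a mouse, a day or a batch is not given in the sources used here.

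Alternatives planned before the data were examined were RLE size factors, no filter and a stricter filter on low counts (1 CPM in 4 libraries), only the libraries compared, a replicate block, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, only genes with a mean of at least 5 CPM for overlaps, and leaving out each of the 15 libraries in turn. Added after the data were seen were leaving out 3 libraries with muscle transcripts, a muscle score as covariate, leaving out 2 KO libraries at room temperature that stood apart, counts thinned to the smallest library total, and the overlap of the KO effect at 29 °C with the housing effect in WT. Simulated data with known changes were drawn around 1 mean per gene, at the spread typical of genes of its level. The extra spread of single genes or libraries was left out, so recovery in the real libraries could be lower. The fit was tested on these simulated data. Of genes changed 4-fold it recovered 97.0%, 92.4%, 97.0%, 93.9% and 83.3% in KO against WT at room temperature, KO against WT at 29 °C, the housing effect in WT, that in KO, and the interaction. Of genes changed 2-fold it recovered 74.6%, 71.6%, 67.2%, 58.2% and 40.3%, and of genes changed 1.5-fold 26.9%, 31.3%, 23.9%, 34.3% and 2.99%, in the same order; 3 to 8 unchanged genes were called per comparison. Gene positions came from the GRCm38 reference, in which 91.3% of the symbols were found.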

Results

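Brown adipose tissue, the fat depot that burns lipid to make heat, was profiled by bulk RNA sequencing in mice lacking DJ-1 in that tissue and in flox controls without the deletion. DJ-1, encoded by Park7, is a redox-sensitive protein that protects cells and mitochondria against oxidative stress. The mice were kept for 8 weeks at room temperature, a mild cold load for a mouse, or at 29 °C, near thermoneutrality, where little heat production is needed. The 15 libraries fell into 4 groups, here called WT (flox control) and KO (DJ-1 knockout) at each temperature: 4 WT and 4 KO at room temperature, and 4 WT and 3 KO at 29 °C. Total estimated counts per library ran from 23977400 to 26789200 in 14 libraries and reached 38801000 in KO at 29 °C replicate 1. Levels are given as CPM, counts scaled to a common library total, mean ± SD over the libraries of a group, and effects as log2 fold change ± SE. The labels give the replicates as separate samples and do not state that each was a separate animal, so p-values measure the spread between these samples.

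Park7 was the first gene examined, because it checks the genotype labels. It lies on chromosome 4 at 150897133 to 150909921 (GRCm38/mm10). At room temperature it measured 109.9 ± 1.65 CPM in WT (n = 4) and 28.2 ± 4.03 CPM in KO (n = 4), or 25.6% of the WT level, and the 2 groups did not overlap (exact permutation test, two-sided, p = 0.0286, the smallest that 70 arrangements allow). At 29 °C the levels were 118 ± 11 CPM in WT (n = 4) and 31.7 ± 5.46 CPM in KO (n = 3), or 26.8% of WT (exact permutation test, two-sided, p = 0.0286, the smallest that 35 arrangements allow). No library of either genotype lay among those of the other. In the edgeR fit the log2 fold changes were -1.97 ± 0.12 (adjusted p = 1.5e-07) and -1.90 ± 0.13 (adjusted p = 1.5e-07). The tissue also holds cells of other types, in which the deletion is not described.

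The first principal component of the log2 CPM values held 56.8% of the variance and parted the room-temperature libraries (scores from -69.3 to -48.1) from WT at 29 °C (72.0 to 91.9), with KO at 29 °C in between (31.0 to 63.7). The second held 13.8%. KO at 29 °C sat at its low end, from -62.9 to -31.3. WT at 29 °C replicate 2 scored -10.7 on it, between its group mates (38.3 to 44.4) and KO at 29 °C. The 2 room-temperature genotypes overlapped on both components, although KO replicates 2 and 4 stood apart from the other 6 on the fourth component (41.3 and 34.1, against -24.7 to -1.19). Transcripts of the mitochondrial genome took 30.2% to 41.6% of counts in WT at 29 °C and 22.7% to 27.4% in the other libraries. At 29 °C skeletal muscle markers took 0.233% of counts in WT replicate 2, 0.0811% in KO replicate 2 and 0.270% in KO replicate 3. They took at most 0.00771% elsewhere.

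**Figure D1:**
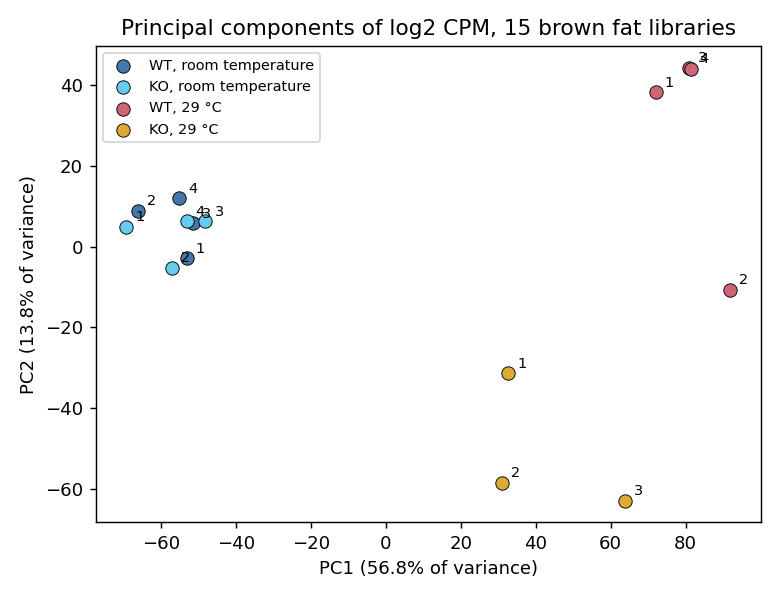
First and second principal components of log2 CPM over the 15083 genes tested, one point per library, coloured by genotype and housing; the axes give each component's share of the variance (56.8% and 13.8%). Room-temperature libraries of both genotypes lie together at the left, WT at 29 °C at the right, and KO at 29 °C between them and lower on the second component.

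The comparison of KO with WT at room temperature asked what loss of DJ-1 changed in brown fat that was working against mild cold. Few genes moved. Among the largest falls besides Park7 itself were those in Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, at 2.87 ± 0.83 CPM in WT and 0.343 ± 0.210 CPM in KO (n = 4 each), and Gem, a small GTP-binding protein that restrains voltage-gated calcium channels (7.02-fold lower). Another was in Btc, the epidermal growth factor receptor ligand betacellulin (4.43-fold lower). The tight-junction protein Cldn5 (2.42-fold lower) and the shear-responsive transcription factor Klf2 (2.39-fold lower) were among them too. The rises were led by Fam46a, a non-canonical poly(A) polymerase (3.42-fold higher), the cell-cycle factor E2f2 (3.28-fold higher) and Arntl, the BMAL1 subunit of the circadian clock activator (2.46-fold higher).

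Of 15083 genes tested with edgeR's quasi-likelihood test, 36 passed an adjusted p of 0.05, 8 higher and 28 lower in KO, and 31 of them changed by more than 1.5-fold. Log2 fold changes were -3.05 ± 0.47 for Ppp1r3g (adjusted p = 0.0152), -2.81 ± 0.30 for Gem (3.2e-04), -2.15 ± 0.18 for Btc (1.2e-05), 1.71 ± 0.18 for E2f2 (1.9e-04), 1.77 ± 0.33 for Fam46a (0.0497) and 1.30 ± 0.25 for Arntl (0.0496). Smaller rises were seen in Rpia, an enzyme of the pentose phosphate pathway (0.75), Elovl5, a fatty acid elongase (0.60), the ribosome-assembly genes Rpf2 (0.56) and Rrp8 (0.50), and Lins1 (0.50), with adjusted p from 0.0159 to 0.0496. Smaller falls were seen in Plekhf1, a lysosome-associated protein (-0.96), the clock repressor Nr1d2 (-0.74), the cyclic-AMP phosphodiesterase Pde4d (-0.89) and the complex I subunit Ndufs7 (-0.61), with adjusted p from 0.0152 to 0.0396. Ucp1, the uncoupling protein that makes brown fat produce heat, measured 8602 ± 1022 CPM in WT and 7001 ± 2502 CPM in KO, a difference that did not pass the test (log2 fold change -0.30 ± 0.21, adjusted p = 0.647). Nor did those in the thyroid-hormone deiodinase Dio2 (-0.94 ± 0.63), the mitochondrial coactivator Ppargc1a (-0.65 ± 0.39), the lysosomal receptor Lamp2 (-0.07 ± 0.11) or its cytosolic partner chaperone Hspa8 (0.32 ± 0.18), with adjusted p from 0.533 to 0.864.

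Counts adjusted over the list alone are given as members higher, then lower. Among the gene lists, circadian clock genes had 1 member higher (Arntl) and 1 lower (Nr1d2) of 15 (1 and 7 adjusted over the list alone), with a median log2 fold change of -0.48 (camera adjusted p = 0.00151, and adjusted p = 0.0985 with an estimated correlation). None of the 27 thermogenic brown fat genes passed over all genes tested or adjusted over the list alone. Their median was -0.24 (camera adjusted p = 3.0e-04, and adjusted p = 0.741 with an estimated correlation). The nuclear subunits of oxidative phosphorylation (OXPHOS) had 1 of 41 lower, Ndufs7 (0 and 1 adjusted over the list alone), and a median of -0.12 (camera adjusted p = 2.4e-07, and adjusted p = 0.741 with an estimated correlation). Cholesterol synthesis had no member past the threshold over all genes tested, against 8 of 19 higher adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.4e-07, and adjusted p = 0.741 with an estimated correlation). De novo lipogenesis, the making of fatty acids from sugar, had 1 of 17 higher, Elovl5 (1 and 0 adjusted over the list alone), and a median of 0.48 (camera adjusted p = 1.1e-04, and adjusted p = 0.741 with an estimated correlation). The interferon response had no member called by either adjustment and a median of 0.99 (camera adjusted p = 1.5e-05, and adjusted p = 0.741 with an estimated correlation). Without KO replicate 3, in which the guanylate-binding gene Gbp10 stood at 21.2 CPM against at most 3.16 in the other 3, the median was 0.06 and the adjusted p = 0.237. Beside the 36 genes called by edgeR, 1678 had an unadjusted p under 0.05, and DESeq2 called 228.

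The KO effect at room temperature rested on individual libraries. The count of 36 fell to 5 without KO replicate 2 or KO replicate 4, 7 without WT replicate 2, 11 without WT replicate 4, 16 without WT replicate 3 and 19 without KO at 29 °C replicate 2. It rose to 58 and 60 without KO replicates 3 and 1. Of the 15 named genes with the largest changes, Park7, E2f2, Gem and Btc passed with any 1 library left out. Without both KO replicates 2 and 4, which stood apart on the fourth component, 5 genes passed and 779 of 15367 had an unadjusted p under 0.05. The thermogenic and de novo lipogenesis medians were -0.04 (adjusted p = 0.388) and 0.08 (adjusted p = 0.354), and both camera calls were lost. The cholesterol synthesis median fell to 0.19 (adjusted p = 0.0189). Camera at its preset correlation still called that list, the nuclear OXPHOS subunits (-0.07), the clock genes (-0.38) and the interferon response (1.55). The interferon call rests on KO replicate 3, which this setting keeps.

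At 29 °C the same comparison asked what loss of DJ-1 changed in brown fat at rest, and here KO and WT differed widely. Ucp1 stood at 1019 ± 203 CPM in WT (n = 4) and 7233 ± 1240.5 CPM in KO (n = 3), 7.10-fold higher, and Dio2 at 47.2 ± 41.3 and 282 ± 90.3 CPM. Most genes of heat production, the tricarboxylic acid (TCA) cycle, fatty acid oxidation, lipid droplets, lipolysis, lysosomes and lymphocytes were higher in KO, and all 12 endothelial markers were lower. Camera called none of these lists with an estimated correlation (adjusted p from 0.243 to 0.276). The heat-shock genes Hspa1a and Hspa1b were 13.7-fold lower and 13-fold lower. Clock genes moved both ways, the output factor Dbp 13.7-fold higher and the activators Npas2 and Arntl 16.9-fold lower and 5.11-fold lower.

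By edgeR's quasi-likelihood test 6747 of 15083 genes passed an adjusted p of 0.05, 3728 higher and 3019 lower in KO, and 4182 of them changed by more than 1.5-fold. The largest rises were in the protease inhibitor Slpi (log2 fold change 4.90 ± 0.50, adjusted p = 4.0e-06), the synaptotagmin Syt12 (3.96 ± 0.33, 1.6e-06), Dbp (3.78 ± 0.40, 1.3e-05), Fam131c (3.76), the soluble adenylyl cyclase Adcy10 (3.72), Gbp10 (3.60), the stress hormone Gdf15 (3.49 ± 0.49, 8.8e-05) and the asparaginase Aspg (3.37). Gbp10 belongs to a family of closely related genes, so its share of reads is uncertain. The largest falls were in Npas2 (-4.08 ± 0.34, adjusted p = 4.5e-07), Hspa1a (-3.78 ± 0.83, 0.00332), Hspa1b (-3.70), Akr1cl (-3.24), the calcium-binding protein Cabp1 (-2.71), Nnat (-2.67), the semaphorin Sema4g (-2.56) and Arntl (-2.35 ± 0.28, 1.3e-05). Hspa1a and Hspa1b are near-identical copies, and the reads cannot be assigned to either with certainty.

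Of 27 thermogenic brown fat genes, 19 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 1.01 (camera adjusted p = 4.5e-06, and adjusted p = 0.243 with an estimated correlation). Examples were Ucp1 (2.83 ± 0.24, adjusted p = 7.9e-07), the lipid-droplet protein Plin5, which couples droplets to mitochondria (1.69), the proton channel Otop1 (1.49) and Letmd1 (1.03). Dio2 (2.58 ± 0.69), Ppargc1a (1.95 ± 0.43) and the fatty acid elongase Elovl3 (2.86 ± 0.71) also rose, with adjusted p from 0.00277 to 0.00984. Cidea, a lipid-droplet fusion protein of brown fat, measured 1567 ± 492 and 1719 ± 123 CPM and did not pass (adjusted p = 0.592). Fatty acid oxidation rose in 18 of 21 and fell in 1 (18 and 1 adjusted over the list alone), median 0.79 (camera adjusted p = 3.0e-07, and adjusted p = 0.276 with an estimated correlation). Hadha, of the trifunctional enzyme, rose by 1.24 and the thioesterase Acot2, whose reads are shared with Acot1, by 1.88. TCA cycle enzymes rose in 14 of 16 (14 and 0 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 2.8e-06, and adjusted p = 0.269 with an estimated correlation). Idh3a (1.22) was among them. Nuclear OXPHOS subunits went both ways, with 18 of 41 higher and 6 lower (19 and 7 adjusted over the list alone), and camera made no call (camera adjusted p = 0.0884, and adjusted p = 0.828 with an estimated correlation). Uqcrc2 (1.10) and Ndufs1 (0.98) were among the higher. Of the 13 mitochondrially encoded genes 6 were lower (0 and 6 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.0490, and adjusted p = 0.828 with an estimated correlation). This call was lost without any of 11 single libraries. Without WT at 29 °C replicate 4, whose mitochondrial share was the highest at 41.6%, the median was -0.19 (adjusted p = 0.343). In the other 10 settings it was -0.58 to -0.48, with adjusted p from 0.0515 to 0.0916. ATP8, at -1.78, overlaps its neighbour ATP6, so its reads are uncertain.

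Some of the lipid-handling lists rose too. Triglyceride synthesis and lipid droplet genes rose in 16 of 19 members (16 and 0 adjusted over the list alone), median 0.72 (camera adjusted p = 4.4e-06, and adjusted p = 0.243 with an estimated correlation). The droplet coat protein Plin1 (1.97 ± 0.13) and the acyltransferase Gpam (1.12) were among them. Lipolysis and beta-adrenergic signalling rose in 13 of 16 (13 and 1 adjusted over the list alone), median 1.07 (camera adjusted p = 3.0e-05, and adjusted p = 0.243 with an estimated correlation). Hormone-sensitive lipase Lipe (1.32) and the adenylyl cyclase Adcy3 (2.08) both rose. Glycolysis rose in 16 of 17 (16 and 0 adjusted over the list alone), median 0.81 (camera adjusted p = 2.2e-05, and adjusted p = 0.243 with an estimated correlation). De novo lipogenesis had 4 of 17 members higher (3 and 0 adjusted over the list alone) and no call by camera (camera adjusted p = 0.243, and adjusted p = 0.828 with an estimated correlation). The elongase Elovl6 (1.15) and the transcription factor Srebf1 (1.15) were among the 4. Fatty acid synthase, Fasn, measured 1179.8 ± 989 CPM in WT and 1972 ± 378 CPM in KO and did not pass (adjusted p = 0.310). The adipocyte regulator Pparg (0.92 ± 0.18) and the adipokine Adipoq (0.53 ± 0.13) were higher. Leptin, Lep, made mainly by white adipocytes, measured 102 ± 37.4 and 129 ± 47.3 CPM and did not pass (adjusted p = 0.747).

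**Figure D2:**
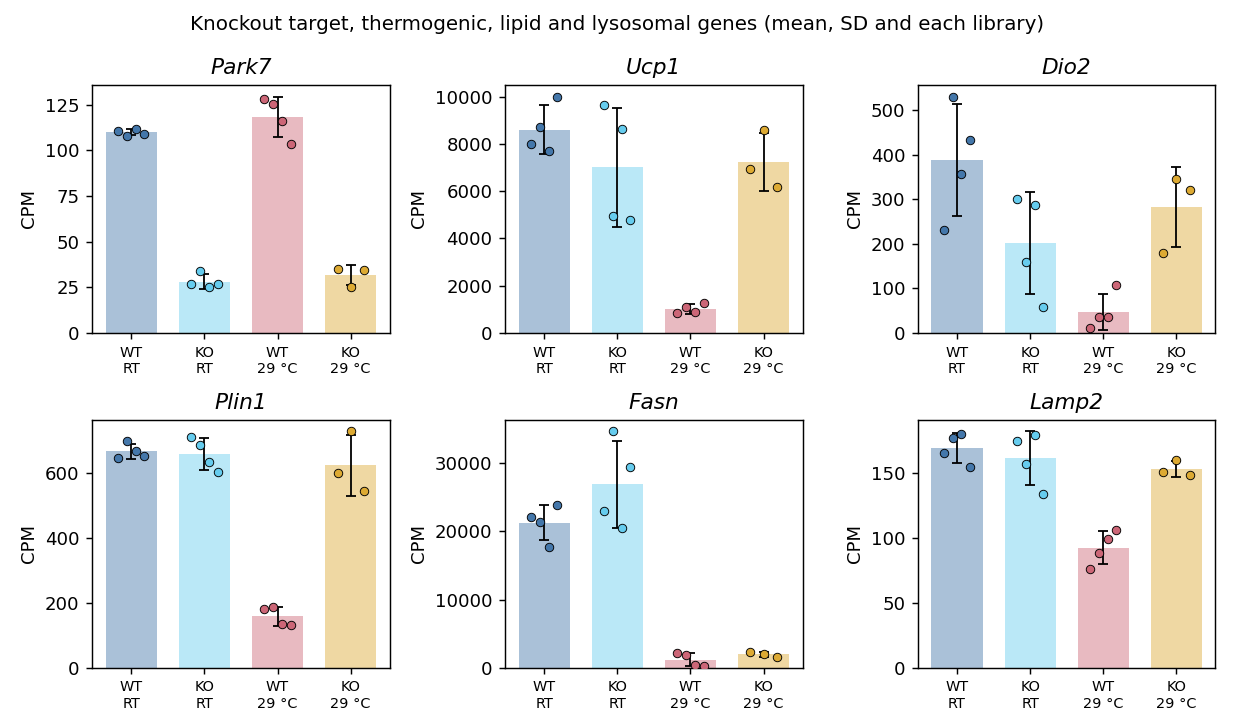
CPM of Park7, Ucp1, Dio2, Plin1, Fasn and Lamp2 in the 4 groups (RT, room temperature); points are libraries, bars the group mean from 0 and error bars the SD. Ucp1 averages 1019 CPM in WT at 29 °C and 7233 CPM in KO at 29 °C, while Fasn is low in both genotypes at 29 °C.

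Chaperone-mediated autophagy, in which Hspa8 carries single proteins to Lamp2 on the lysosome, is the process the study's title names. Its list had 5 members higher and 5 lower of 25 (5 and 5 adjusted over the list alone), with a median of 0.12 and no call by camera (camera adjusted p = 0.494, and adjusted p = 0.828 with an estimated correlation). Lamp2 rose from 92.7 ± 13 to 153 ± 6.26 CPM (log2 fold change 0.73 ± 0.12, adjusted p = 1.2e-04), as did the sorting nexin Snx10 (1.74) and the Hsp70-interacting protein St13 (1.08), whereas Hspa8 fell by 0.83 on the log2 scale (adjusted p = 0.00273). The deposited counts are per gene, so the Lamp2 isoforms cannot be told apart here. Lysosomal enzymes and membrane proteins rose in 21 of 30 and fell in 2 (22 and 2 adjusted over the list alone), median 0.48 (camera adjusted p = 1.2e-05, and adjusted p = 0.243 with an estimated correlation). The cholesterol transporter Npc1 (1.65) and the protease Ctsb (0.93) were higher. Macroautophagy and mitophagy genes rose in 15 of 28 and fell in 2 (15 and 2 adjusted over the list alone), median 0.35 (camera adjusted p = 0.00680, and adjusted p = 0.328 with an estimated correlation). Gabarapl1 rose by 1.0. Of the genes of mitochondrial biogenesis and dynamics 12 of 17 rose and 2 fell (12 and 2 adjusted over the list alone), median 0.52 (camera adjusted p = 9.3e-04, and adjusted p = 0.276 with an estimated correlation). The mitochondrial DNA-packaging factor Tfam rose by 1.11 ± 0.10. Antioxidant genes and targets of the redox factor NRF2 rose in 18 of 28 (19 and 2 adjusted over the list alone), median 0.60 (camera adjusted p = 3.5e-05, and adjusted p = 0.269 with an estimated correlation). Catalase, Cat, rose by 1.07. The integrated stress response had 8 of 21 higher and 3 lower (8 and 3 adjusted over the list alone) and no call by camera (camera adjusted p = 0.132, and adjusted p = 0.461 with an estimated correlation). Asparagine synthetase Asns (1.30) and the mitochondrial folate enzyme Mthfd2 (1.83) were among those that rose.

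Markers of other cell types differed as well. Lymphocyte markers rose in 13 of 16 (13 and 0 adjusted over the list alone), median 1.65 (camera adjusted p = 1.8e-04, and adjusted p = 0.243 with an estimated correlation). The T-cell receptor subunit Cd3e went from 0.248 ± 0.0117 to 2.14 ± 0.816 CPM and Cd8a from 1.15 ± 0.177 to 5.0 ± 2.14 CPM. Endothelial markers fell in 12 of 12 (0 and 12 adjusted over the list alone), median -1.2 (camera adjusted p = 9.2e-08, and adjusted p = 0.243 with an estimated correlation). Egfl7 (-1.63 ± 0.15) and the angiopoietin receptor Tek (-1.33 ± 0.13) were 2 of them. Of 20 macrophage markers 8 rose and 2 fell (8 and 2 adjusted over the list alone), with no call by camera (camera adjusted p = 0.123, and adjusted p = 0.828 with an estimated correlation). Cd68 (1.37) rose and Cd163 (-1.37) fell. Skeletal muscle markers were high in 1 of the 4 WT libraries and 2 of the 3 KO libraries at 29 °C. Without those 3 libraries, which leaves a single KO library assumed to vary like the others, 4229 genes passed (2110 higher and 2119 lower) and 8 of the 27 thermogenic genes were higher, with a median of 0.81. All 12 endothelial markers were still lower. With a muscle score in the fit instead, 6019 genes passed, with 19 thermogenic genes higher and 12 endothelial markers lower. All 16 of the genes with the largest changes passed with any 1 library left out.

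Housing at 29 °C compared with room temperature in WT measured how the normal tissue responds to the loss of its cold load. It was the largest contrast in the series. Most genes of heat production and de novo lipogenesis fell. Ucp1 went from 8602 ± 1022 to 1019 ± 203 CPM (n = 4 each), 8.44-fold lower, and Fasn from 21269 ± 2589.5 to 1179.8 ± 989 CPM, 18-fold lower. Most markers of cell division, macrophages and endothelium rose. Camera called none of these 5 lists with an estimated correlation (adjusted p from 0.210 to 0.373). The inducible heat-shock genes Hspa1a and Hspa1b rose from 2.47 ± 1.10 to 304 ± 147 CPM and from 3.52 ± 2.03 to 278 ± 161 CPM. Leptin rose from 15.3 ± 14.3 to 102 ± 37.4 CPM.

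edgeR's quasi-likelihood test called 10375 of 15083 genes, 5421 higher and 4954 lower at 29 °C, 7744 of them by more than 1.5-fold. The largest rise outside muscle genes was in Akr1cl, which had no count in any room-temperature library and averaged 6.60 ± 3.26 CPM at 29 °C (at least 208-fold higher, against a floor of 3 counts over the group). Next came Hspa1a (log2 fold change 6.94 ± 0.89, adjusted p = 2.5e-05), Hspa1b (6.30 ± 0.90), the copine Cpne9 (6.12), placental growth factor Pgf (6.05) and macrophage elastase Mmp12 (5.86). Among the largest falls were those in Adcy10 (-6.89 ± 0.44, adjusted p = 2.9e-09), Dnajc22 (-6.63), Aspg (-6.31), the proton pump subunit Atp4b (-5.86), Elovl3 (-5.29 ± 0.71), the thioesterase Acot1 (-5.08, with reads shared with Acot2) and Adprhl1 (-5.03). The muscle genes Tnnc2 and Acta1 also met the rule for the largest rises, but both calls came from WT replicate 2, where they stood at 122 and 199 CPM against at most 1.14 and 0.763 in its 3 group mates. Without it their log2 fold changes were 3.06 and 2.09 and their adjusted p 0.177 and 0.436.

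Thermogenic brown fat genes fell in 24 of 27 (0 and 25 adjusted over the list alone), with a median log2 fold change of -1.62 (camera adjusted p = 5.5e-07, and adjusted p = 0.210 with an estimated correlation). Ucp1 fell by 3.08 on the log2 scale (adjusted p = 1.7e-08), and Dio2 (-3.04 ± 0.68), Ppargc1a (-2.66 ± 0.42) and Otop1 (-2.89 ± 0.13) fell too. Cidea, at -0.49 ± 0.17 (adjusted p = 0.0201), lost its call without WT at 29 °C replicate 3 or 4 (-0.35 and -0.39, adjusted p up to 0.0704). TCA cycle enzymes fell in 16 of 16 (0 and 16 adjusted over the list alone), median -1.29 (camera adjusted p = 8.1e-08, and adjusted p = 0.210 with an estimated correlation). De novo lipogenesis fell in 16 of 17 (0 and 16 adjusted over the list alone), median -2.32 (camera adjusted p = 4.2e-06, and adjusted p = 0.297 with an estimated correlation). Fasn changed by -4.17 ± 0.60 and Elovl6 by -3.91 ± 0.22. Glycolysis fell in 16 of 17 and rose in 1 (1 and 16 adjusted over the list alone), median -1.61 (camera adjusted p = 1.8e-06, and adjusted p = 0.210 with an estimated correlation). Chaperone-mediated autophagy had 7 higher and 9 lower of 25 (6 and 9 adjusted over the list alone) and no call by camera (camera adjusted p = 0.367, and adjusted p = 0.695 with an estimated correlation).

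In the other direction, the cell cycle list rose in 15 of 16 (15 and 0 adjusted over the list alone), median 2.47 (camera adjusted p = 1.2e-04, and adjusted p = 0.276 with an estimated correlation). The proliferation marker Mki67 (3.84 ± 0.39) and the kinase Cdk1 (3.69 ± 0.38) were among them. Macrophage markers rose in 17 of 20 and fell in 1 (17 and 1 adjusted over the list alone), median 1.34 (camera adjusted p = 3.6e-04, and adjusted p = 0.373 with an estimated correlation). The integrin Itgax rose by 3.18 ± 0.33. All 12 endothelial markers rose (12 and 0 adjusted over the list alone), median 1.29 (camera adjusted p = 3.0e-05, and adjusted p = 0.296 with an estimated correlation). Cldn5 went from 53.2 ± 21 to 296 ± 20.6 CPM. Cytosolic ribosomal proteins rose in 24 of 26 and fell in 1 (24 and 1 adjusted over the list alone), median 0.60 (camera adjusted p = 1.5e-06, and adjusted p = 0.373 with an estimated correlation). White adipocyte genes, a list that also holds genes of lipid-laden fat, had 8 higher and 3 lower of 20 (6 and 1 adjusted over the list alone) and no call by camera (camera adjusted p = 0.367, and adjusted p = 0.695 with an estimated correlation). The growing-fat marker Mest (3.95 ± 0.37), the lipid-associated macrophage receptor Trem2 (4.15 ± 0.54) and Lep (2.74 ± 0.77) were among those that rose.

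In KO mice the same change of housing measured whether the response of the tissue to warmth took place without DJ-1. Ucp1 was not called: it measured 7001 ± 2502 CPM at room temperature (n = 4) and 7233 ± 1240.5 CPM at 29 °C (n = 3; log2 fold change 0.05 ± 0.23, adjusted p = 0.887), a difference that did not pass the edgeR test. Fasn did fall, from 26914 ± 6386 to 1972 ± 378 CPM (13.6-fold lower) and ATP citrate lyase Acly from 5991 ± 2990.2 to 289.9 ± 80.8 CPM (20.7-fold lower). The integrin Itgax (12.8-fold higher), the serine synthesis enzyme Phgdh (8.10-fold higher) and Mthfd2 (4.6-fold higher) rose.

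The test called 6940 genes, 3664 higher and 3276 lower at 29 °C, 4374 of them by more than 1.5-fold. Among the largest falls were those in the multicopper oxidase Hephl1 (log2 fold change -5.69 ± 0.87, adjusted p = 1.4e-04), the potassium channel subunit Kcng4 (-4.79), Dnajc22 (-4.75), the aryl hydrocarbon receptor target Cyp1a1 (-4.66 ± 0.57, 4.4e-05), Acly (-4.37 ± 0.58, 7.5e-05), the fructose transporter Slc2a5 (-4.13) and Rims4 (-4.06). The 8 largest rises were all in muscle genes, Myh4, Mybpc1, Actn3, Tnnt3, Atp2a1, Tnnc2, Ppp1r3a and Tnni2. They came from KO at 29 °C replicates 2 and 3: Acta1 stood at 108 and 302 CPM there, 2.66 CPM in replicate 1 and at most 0.379 CPM at room temperature. Each of the 8 calls was lost without replicate 3 (adjusted p over any 1 library left out up to 0.180 for Myh4). Without the 3 libraries with muscle transcripts 4129 genes passed, and with a muscle score in the fit 4157 did.

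De novo lipogenesis fell in 16 of 17 (0 and 16 adjusted over the list alone), with a median log2 fold change of -2.38 (camera adjusted p = 3.3e-10, and adjusted p = 0.283 with an estimated correlation). Cholesterol synthesis fell in 16 of 19 (0 and 16 adjusted over the list alone), median -1.54 (camera adjusted p = 1.4e-07, and adjusted p = 0.283 with an estimated correlation). Thermogenic brown fat genes had 3 higher and 9 lower of 27 (3 and 9 adjusted over the list alone) and a median of -0.38 (camera adjusted p = 0.0293, and adjusted p = 0.564 with an estimated correlation). The preset call was lost without KO at room temperature replicate 1 (median -0.31, adjusted p = 0.0774) or 3 (median -0.41, adjusted p = 0.111). Elovl3 fell among them (-3.34 ± 0.68). The integrated stress response rose in 13 of 21 (13 and 0 adjusted over the list alone), median 1.02 (camera adjusted p = 0.00106, and adjusted p = 0.283 with an estimated correlation). Its secreted member Gdf15 went from 0.143 ± 0.102 to 18.8 ± 13.8 CPM. Lymphocyte markers rose in 16 of 16 (16 and 0 adjusted over the list alone), median 2.25 (camera adjusted p = 2.4e-07, and adjusted p = 0.283 with an estimated correlation). Macrophage markers rose in 17 of 20 (18 and 0 adjusted over the list alone), median 1.30 (camera adjusted p = 3.1e-07, and adjusted p = 0.283 with an estimated correlation). Inflammatory cytokines and receptors rose in 15 of 18 (15 and 0 adjusted over the list alone), median 2.47 (camera adjusted p = 7.7e-07, and adjusted p = 0.283 with an estimated correlation). Skeletal muscle markers had 14 of 18 higher (16 and 0 adjusted over the list alone) (camera adjusted p = 2.5e-04, and adjusted p = 0.564 with an estimated correlation). Chaperone-mediated autophagy had 5 higher and 4 lower of 25 (5 and 4 adjusted over the list alone) and no call by camera (camera adjusted p = 0.590, and adjusted p = 0.769 with an estimated correlation).

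Across genes, the 2 housing effects went together. Of the genes tested, 2876 rose at 29 °C in both genotypes, where 1317 would be shared by independent lists, and 2658 fell in both, against 1076. Genes are not independent replicates. Pearson's r of the log2 fold changes across genes was 0.756, and 0.646 without WT at 29 °C replicate 2. Opposite calls were made for 85 genes higher in WT and lower in KO and for 131 lower in WT and higher in KO. The KO effects at the 2 temperatures hardly correlated across genes (r = 0.0627). Few genes were called at room temperature, so noise in those fold changes could by itself keep r low. Of the 28 genes lower in KO at room temperature, 12 were higher in KO at 29 °C, with 6.92 given by independent lists (one-sided Fisher's exact p = 0.0269). Lower at both were 7, among them the deleted gene Park7 itself, with 5.6 given by independent lists (one-sided Fisher's exact p = 0.322). Of the 8 genes higher in KO at room temperature, 2 were higher and 3 lower in KO at 29 °C. Independent lists give 1.98 and 1.60 (one-sided Fisher's exact p = 0.626 and 0.203). The p-values were not adjusted for the overlaps tested.

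The interaction tested directly whether the KO effect differed between the 2 temperatures. It did for 19 of 27 thermogenic brown fat genes, although the camera call on the list was lost with an estimated correlation (adjusted p = 0.183). Ucp1 measured 8602 and 7001 CPM in WT and KO at room temperature but 1019 and 7233 CPM at 29 °C, and the KO effect on its log2 level was 3.12 higher at 29 °C. The same held for Dio2 (3.53), Ppargc1a (2.61) and Lamp2 (0.80), while Hspa8 went the other way (-1.15). Ppp1r3g was lower in KO at room temperature and higher in KO at 29 °C. Irs2, which carries the insulin signal, measured 79.1 ± 18.2 CPM in WT and 16.9 ± 14.3 CPM in KO at room temperature, a difference that did not pass. At 29 °C Irs2 measured 4.40 ± 3.55 CPM in WT and 24.7 ± 10.8 CPM in KO and was higher in KO. Arntl was higher in KO at room temperature and lower in KO at 29 °C, while Dbp was called at 29 °C alone, where it was higher in KO.

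By the edgeR test 4272 genes had a KO effect that differed between temperatures, 2416 with a more positive effect at 29 °C and 1856 with a more negative one, 3260 of them by more than 1.5-fold. The largest positive interactions were in the lysophosphatidylcholine transporter Mfsd2a (5.82 ± 1.63, adjusted p = 0.0200), Ppp1r3g (5.08 ± 0.74, 1.6e-04), Slpi (4.92 ± 1.32, 0.0125), Dbp (4.80 ± 0.52, 6.2e-05) and the insulin receptor substrate Irs2 (4.71 ± 0.93, 0.00330). The largest negative ones were in Npas2 (-4.58 ± 0.42, 7.4e-06), Hspa1a (-3.98 ± 1.16, 0.0240), E2f2 (-3.74 ± 0.26, 8.1e-07), Hspa1b (-3.69 ± 1.18, 0.0363) and Arntl (-3.65 ± 0.37, 2.0e-05). Mfsd2a lost its call without KO at 29 °C replicate 3 (4.22, adjusted p = 0.0668) and Slpi without WT at room temperature replicate 1 (4.19, 0.0984). Hspa1a lost it without KO at room temperature replicate 2 or KO at 29 °C replicate 1 (-3.51 and -3.59, up to 0.0590), and Hspa1b without any of 9 single libraries (-3.06 at the smallest, up to 0.0902).

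**Figure D3:**
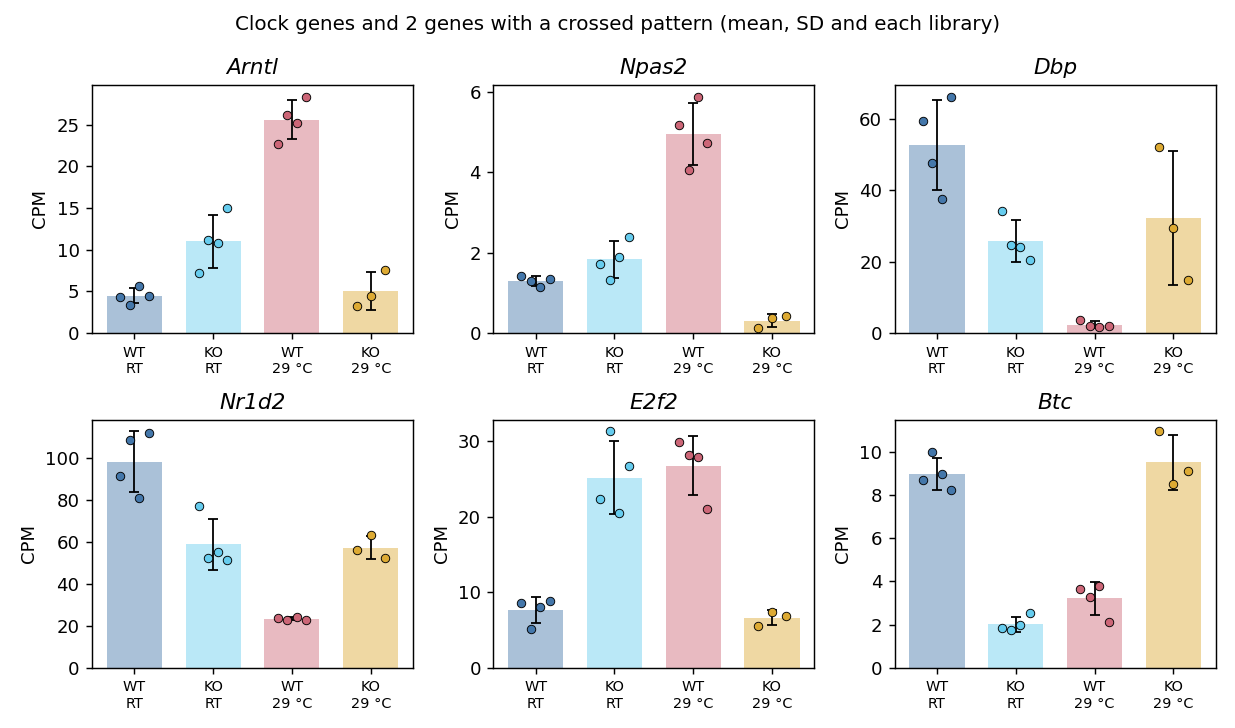
CPM of the clock genes Arntl, Npas2, Dbp and Nr1d2 and of E2f2 and Btc in the 4 groups (RT, room temperature); points are libraries, bars the group mean from 0 and error bars the SD. Arntl and E2f2 average 4.49 and 7.67 CPM in WT against 11 and 25.2 CPM in KO at room temperature, and 25.6 and 26.8 CPM in WT against 5.04 and 6.61 CPM in KO at 29 °C.

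Thermogenic brown fat genes had 19 of 27 members with a more positive KO effect at 29 °C and 0 with a more negative one (20 and 0 adjusted over the list alone), with a median interaction of 1.27 (camera adjusted p = 2.3e-08, and adjusted p = 0.183 with an estimated correlation). Fatty acid oxidation had 19 of 21 more positive (20 and 0 adjusted over the list alone), median 0.97 (camera adjusted p = 2.6e-10, and adjusted p = 0.183 with an estimated correlation). Lipolysis and beta-adrenergic signalling had 11 of 16 (13 and 0 adjusted over the list alone), median 1.21 (camera adjusted p = 3.5e-06, and adjusted p = 0.183 with an estimated correlation). Endothelial markers had 11 of 12 more negative (0 and 11 adjusted over the list alone), median -0.97 (camera adjusted p = 1.9e-06, and adjusted p = 0.221 with an estimated correlation). Cholesterol synthesis had 9 of 19 more negative (0 and 10 adjusted over the list alone), median -0.69 (camera adjusted p = 4.4e-04, and adjusted p = 0.422 with an estimated correlation). Circadian clock genes had 7 of 15 more positive and 3 more negative (9 and 4 adjusted over the list alone) and no call by camera (camera adjusted p = 0.0526, and adjusted p = 0.183 with an estimated correlation). De novo lipogenesis had 1 more positive and 1 more negative of 17 (1 and 1 adjusted over the list alone), with no call by camera (camera adjusted p = 0.779, and adjusted p = 0.921 with an estimated correlation).

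**Figure D4:**
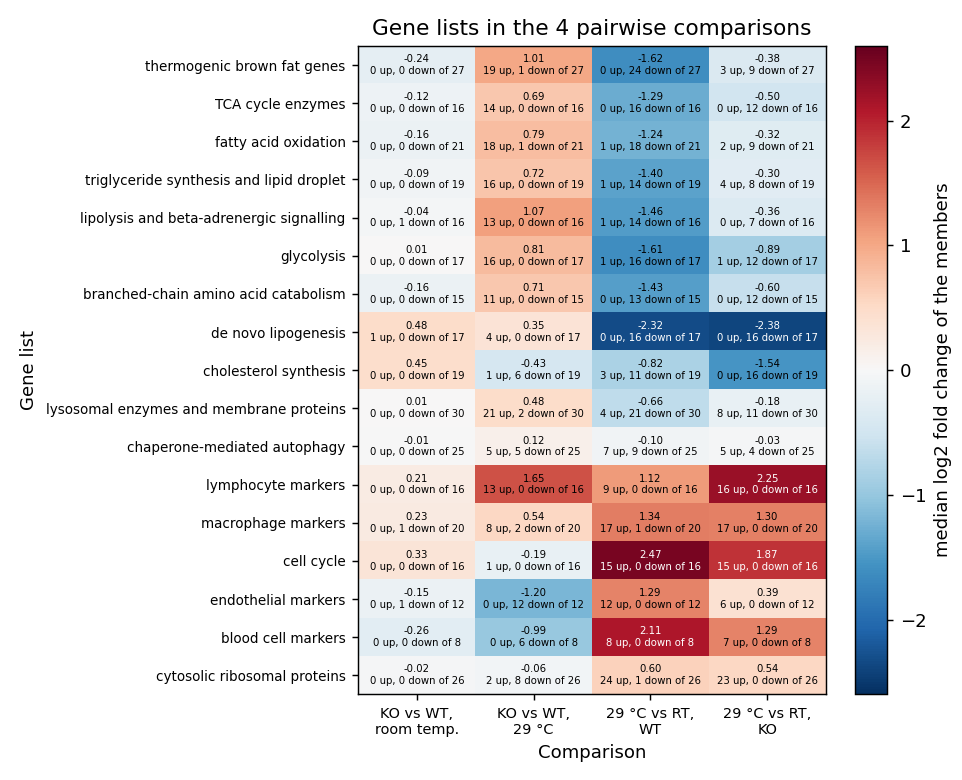
Median log2 fold change of each gene list in the 4 pairwise comparisons, coloured from lower to higher, with the numbers of members higher and lower in each cell. The thermogenic list reads -1.62 for 29 °C against room temperature in WT, -0.38 in KO, and 1.01 for KO against WT at 29 °C.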

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

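Of the tests of explanations here, those of swapped housing, the share of brown adipocytes and collection time were chosen only after the results were seen. So was that of a genotype or housing effect on muscle genes. The muscle score was added after the data were seen, and the 3 libraries with muscle transcripts were picked from the data.

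The KO effect differed between the 2 temperatures for 4272 genes in the edgeR interaction test, and for 67 of the 104 genes named. In none of the 5 counts did another split give as many genes as the real one, and 1 of 35 is the smallest share that 35 splits allow. The real split gave 36 genes for KO against WT at room temperature (highest other 2, 1 of 35 splits gave as many). It gave 6747 for KO against WT at 29 °C (highest other 3076, 1 of 35). The housing effect gave 10375 in WT (highest other 0, 1 of 35) and 6940 in KO (highest other 3756, 1 of 35). The interaction gave 4272 (highest other 3775, 1 of 100 relabellings drawn). Those relabellings moved genotype within each temperature, so they test for any genotype effect and cannot single out the interaction. The highest other splits of KO against WT at 29 °C, of the housing effect in KO and of the interaction all kept the 3 KO libraries at 29 °C together, and those that parted them gave at most 144, 12 and 31 genes.

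The first pattern weighed was the higher level of thermogenic genes in KO than in WT at 29 °C. Had the KO libraries come from mice kept at room temperature throughout, the de novo lipogenesis genes should have stayed near their room-temperature level. Their median log2 fold change was -2.38 (quartiles -2.99 and -2.03), which argues against such a full swap and covers no shorter change of housing. Muscle transcripts in 3 libraries are argued against by the 19 thermogenic genes higher with a muscle score in the fit, although 8 were called without those libraries, with 1 KO library left and a median of 0.81. A larger share of brown adipocytes and no other change would lower the markers of every other cell type. The lymphocyte median exceeded the endothelial one by 2.85 (quartiles 1.2 to 2.15 and -1.41 to -0.997). Lymphocytes may have differed by themselves while the endothelial markers fell, so these values cannot decide whether that share was larger. An effect of DJ-1 loss at 29 °C may lie behind the pattern, as a hypothesis found and tested on the same libraries. The share of brown adipocytes and the batches, collection times and food intake of the groups stay open.

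The second pattern was in the clock genes, 10 of 15 of which passed the interaction test with estimated KO effects of opposite sign at the 2 temperatures. Only Arntl and Nr1d2 passed at both temperatures, and camera made no interaction call for the list (adjusted p = 0.0526). Groups collected at different times of day could give the pattern. The median of 9 clock genes, Dbp and Nr1d2 among them, was set against that of 5 others, Arntl and Npas2 among them. Those 5 are not all activators, as they hold repressors too. The first median minus the second was 1.97 at 29 °C and -1.24 at room temperature. Collection time is confounded with the groups, so it and an effect of genotype that depends on temperature cannot be told apart here.

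The third pattern was the high level of skeletal muscle genes in 3 of the 7 libraries at 29 °C. Muscle tissue taken with the fat is a candidate explanation: over the 18 markers the lowest pairwise Pearson r of log2 CPM between the 3 libraries was 0.853 and the highest 0.940. Acta1 stood at 108 CPM or more in those 3 and at 0.553 to 2.66 CPM in the other 4 libraries at 29 °C, against at most 0.379 CPM at room temperature. All of those 4 libraries lay above the highest at room temperature in 4 of the 18 markers. A smaller effect of housing or genotype on these genes, or traces of muscle in the other libraries, therefore stays open.

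A library stood far from its group mates in 32 of 316 groups of 4 tested by Dixon's ratio of the gap to the range, at the 95% critical value for 4 libraries. In 9 of them no library of the group held 10 counts, a limit chosen only after the results were seen, so the gap was a few reads at most. In 7 of the 32 only 1 library held any count, which makes the ratio 1 by construction. Of the 281 groups with at least 10 counts in a library 23 had such a library, and chance alone gives about 1 in 20 for independent values. The muscle genes and the muscle marker share of WT at 29 °C replicate 2 are among the 23 and are not independent, so no excess of such libraries can be read from the count. The ratio is given first, then the library's CPM against the range of the other 3. KO at room temperature replicate 1 stood apart in Nr1d2 (0.85; 76.8 against 51.2 to 55), Atp2a1 (0.932; 0.0431 against 0.121 to 0.127, lowest), Tnni2 (0.956; 0 against 0.0403 to 0.0422, lowest) and Mfsd2a (0.888; 5.82 against 0.122 to 0.759). KO at room temperature replicate 2 stood apart in Npc1 (0.913; 45.4 against 52.7 to 53.4, lowest), Cd8a (0.848; 1.39 against 0.517 to 0.650), Myh4 (1; 0.0422 against 0) and Actn3 (1; 0.0422 against 0). KO at room temperature replicate 3 stood apart in Gbp10 (0.98; 21.2 against 2.80 to 3.16). WT at room temperature replicate 1 stood apart in Lep (0.956; 36.8 against 7.64 to 8.92), Cdk1 (0.976; 0.290 against 0.126 to 0.130) and Ppp1r3a (1; 0.166 against 0). WT at room temperature replicate 2 stood apart in Hadha (0.926; 2363 against 2103 to 2122) and Mfsd2a (0.831; 36.0 against 5.21 to 10.4). WT at room temperature replicate 4 stood apart in Mybpc1 (1; 0.0866 against 0) and Tnnt3 (1; 0.0433 against 0). WT at 29 °C replicate 1 stood apart in Dbp (0.864; 3.68 against 1.73 to 1.99). WT at 29 °C replicate 2 stood apart in Cd3e (0.968; 0.266 against 0.242 to 0.243), Tnnc2 (0.993; 122 against 0.347 to 1.14), Acta1 (0.999; 199 against 0.553 to 0.763), Adprhl1 (0.905; 0.797 against 0.0694 to 0.138), Myh4 (1; 260.5 against 0), Mybpc1 (0.999; 23.2 against 0 to 0.0346), Actn3 (0.999; 37.6 against 0.0404 to 0.0694), Tnnt3 (0.999; 139.6 against 0.0346 to 0.242), Atp2a1 (0.999; 128 against 0.104 to 0.202), Ppp1r3a (1; 2.62 against 0), Tnni2 (0.999; 89.8 against 0 to 0.104) and the muscle marker share (0.986; 0.233% against 0.00434% to 0.00755%). WT at 29 °C replicate 3 stood apart in Irs2 (0.865; 9.68 against 2.29 to 3.29). WT at 29 °C replicate 4 stood apart in Rrp8 (0.84; 11.3 against 8.92 to 9.30) and Gpam (0.879; 133 against 117 to 119).

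Of the interaction calls of 67 named genes, 55 held with any 1 library left out and 12 were lost in at least 1 such setting. The KO effect on log2 level at 29 °C minus that at room temperature passed the interaction test in these 67 named genes. It was positive in 48: Mfsd2a 5.82, Ppp1r3g 5.08, Slpi 4.92, Dbp 4.80, Irs2 4.71, Fam131c 4.24, Syt12 3.81, Gem 3.73, Btc 3.71, Gdf15 3.70, Dio2 3.53, Aspg 3.49, Ucp1 3.12, Acot1 3.09, Adcy10 2.96, Ppargc1a 2.61, Cd3e 2.52, Atp4b 2.52, Pde4d 2.22, Adcy3 2.20, Nr1d2 2.03, Npc1 2.0, Plin1 1.99, Acot2 1.95, Plin5 1.86, Snx10 1.78, Cd8a 1.73, Otop1 1.65, Plekhf1 1.50, Lipe 1.45, Mthfd2 1.42, Idh3a 1.36, Hadha 1.28, Gpam 1.27, Tfam 1.27, Gabarapl1 1.22, Uqcrc2 1.17, Letmd1 1.15, Cd68 1.15, Cat 1.11, Asns 1.09, St13 1.07, Ndufs1 1.0, Pparg 0.94, Elovl6 0.92, Ctsb 0.81, Lamp2 0.80, Adipoq 0.58. It was negative in 19: Npas2 -4.58, Hspa1a -3.98, E2f2 -3.74, Hspa1b -3.69, Arntl -3.65, Nnat -2.84, Sema4g -2.66, Pgf -2.45, Cpne9 -2.18, Cabp1 -2.09, Fam46a -1.88, ATP8 -1.69, Cd163 -1.31, Egfl7 -1.22, Hspa8 -1.15, Tek -1.10, Rpia -0.96, Elovl5 -0.89, Lins1 -0.83. Camera at its preset correlation called 17 lists in the interaction, none of which it called with an estimated correlation, with median interactions of thermogenic brown fat genes 1.27, nuclear OXPHOS subunits 0.33, TCA cycle enzymes 0.78, fatty acid oxidation 0.97, triglyceride synthesis and lipid droplet 1.06, lipolysis and beta-adrenergic signalling 1.21, adipogenic regulators and adipokines 0.58, cholesterol synthesis -0.69, macroautophagy and mitophagy 0.44, lysosomal enzymes and membrane proteins 0.50, antioxidant and NRF2 targets 0.43, mitochondrial biogenesis and dynamics 0.51, branched-chain amino acid catabolism 0.84, glycolysis 0.71, lymphocyte markers 1.50, endothelial markers -0.97, proteasome 0.26. The proteasome call was lost without KO at 29 °C replicate 1 (median 0.150, camera adjusted p = 0.206) and without several other single libraries.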

How the results depend on the processing

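The settings without the 3 libraries with muscle transcripts, with a muscle score as covariate, without the 2 KO libraries at room temperature that stood apart, and with thinned counts were tests chosen only after the results were seen, as was the overlap of the KO effect at 29 °C with the housing effect in WT.

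The count of 36 genes for KO against WT at room temperature became 228 with DESeq2, 4 at an adjusted p under 0.01, 13 without the 3 muscle libraries and 5 without the 2 KO libraries that stood apart, and ran from 5 to 60 with 1 library left out: 5 without KO replicate 2 or 4, 7 without WT replicate 2, 11 without WT replicate 4, 16 without WT replicate 3, 19 without KO at 29 °C replicate 2, 58 without KO replicate 3 and 60 without KO replicate 1. RLE size factors gave 2 higher and 28 lower, limma-voom 39 and the replicate block 25. The 6747 genes for KO against WT at 29 °C became 4229 without the muscle libraries and 4182 with a fold over 1.5; the 6940 for the housing effect in KO became 4129, 4374 and, with the muscle score, 4157. The interaction gave 2304 of 4272 at an adjusted p under 0.01. With 1 library left out these 3 counts ran from 5374 to 6725, 5490 to 7273 and 3277 to 4563, and the 10375 for the housing effect in WT from 9781 to 10529. The excess of higher genes was not stable. For KO against WT at 29 °C, 3204 were higher and 3390 lower without KO at room temperature replicate 3, 3030 and 3202 with no filter, and 2635 and 2689 with only the libraries compared. For the housing effect in KO, 3162 were higher and 3580 lower without that replicate, and 3175 and 3560 with no filter.

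Across genes, r between the 2 housing effects was 0.646 to 0.776 with 1 library left out (lowest without WT at 29 °C replicate 2) and 0.609 without the muscle libraries. That between the KO effect at room temperature and the housing effect in WT was 0.0320 to 0.210 (highest without WT at room temperature replicate 1) and -0.000113 without the 2 KO libraries. That between the KO effect at 29 °C and the housing effect in WT was -0.702 over genes of at least 5 CPM and -0.361 as the mean with the shared libraries split.

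Signs reversed for muscle genes, as the setting removes muscle signal by construction: in the housing effect in WT, Actn3 (-0.72), Ppp1r3a (-4.37) and Atp2a1 (-2.42) with the muscle score and Atp2a1 (-0.85) without the muscle libraries, with -0.84 to 7.32 over single libraries left out, lowest without WT at 29 °C replicate 2; and Atp2a1 in KO (-0.54) with the score. The interferon list in KO had a median of -0.0909 without the 2 KO libraries. For the other changed results the cause was not tested.

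Of 518 values of named genes, 511 kept their direction and side of the threshold with RLE size factors, 506 with DESeq2, 488 with limma-voom, 497 with no filter, 499 with the replicate block and 514 with thinned counts; with 1 library left out, 7453 of 7755 did. Of 195 list results 97 did with an estimated correlation, which ended all 98 camera calls. Replicate numbers gave no clear pairing of libraries. Of 21 same-number pairs 4 had r above 0.1, and their median r was 0.0378, against -0.0106 for other pairs. Of 15 libraries 7 had their highest r with one of their own number. In every other group 0 of 15 matched best with their own number. No chance value was computed for these counts, so a weak pairing is not excluded. The block is given here alone. Thinned counts gave 33, 6652, 10295, 6763 and 4188 genes. Of simulated 1.5-fold changes, with depth not varied, 2.99% to 34.3% were recovered.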

Other observations

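The overlap of the KO effect at 29 °C with the housing effect in WT was a test chosen only after the results were seen; the other tests given here were chosen before.

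Genes that 29 °C lowered in WT were often those higher in KO at 29 °C, Ucp1 and Plin1 among them. Of the 3728 genes higher in KO at 29 °C, 2960 fell with warm housing in WT (1224 by independent lists), and of the 3019 lower in KO, 2576 rose with it (1085 by independent lists), Egfl7 among them. Pearson's r across genes was -0.542; genes are not independent replicates. WT at 29 °C enters both comparisons, which can by itself give a negative r. The covariance of the log2 fold changes was -0.510. In 100 simulations the other groups were drawn around the observed mean of WT at 29 °C. The simulated r averaged -0.127 and the covariance -0.0119. Such draws leave out the sampling error of the shared libraries, and fold changes in them are small. Neither simulated value can therefore measure what sharing gives or be set against the observed one. With the 4 libraries of WT at 29 °C split into 2 and 2, so that none was shared, r averaged -0.361 over 6 splits (-0.573 to -0.161). The splits gave means of 2392 and 2021 genes in the same 2 overlaps, where 5746 genes on average were called for the KO effect.

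For the KO effect at room temperature and the housing effect in WT, which share WT at room temperature, r was 0.0930. It averaged 0.0278 with those libraries split. The covariance was 0.0491, against a mean of 0.0180 with the libraries split (-0.0365 to 0.0668). In 100 simulations with the other groups drawn around the observed mean of WT at room temperature, r averaged 0.0717 (-0.0152 to 0.164). The covariance averaged 0.00493 there (highest 0.0122). These draws too leave out the sampling error of the shared libraries and hold small fold changes. The simulated values can therefore not be set against the observed ones. Of the 28 genes lower in KO at room temperature 19 also fell with warm housing in WT, with 9.20 given by independent lists. The 6 splits called 8.33 genes on average for the KO effect instead of 36, and gave a mean of 4.33 in this overlap.

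Alleles carried along with the deleted gene could make genes near Park7 differ at both temperatures. Of 159 tested genes within 10 Mb of Park7, 4 (2.52%) had an unadjusted p under 0.05 in edgeR and the same sign at both temperatures, against 483 of 14112 (3.42%) elsewhere (one-sided Fisher's exact p = 0.796). The controls were flox mice, which could carry the same alleles around the gene, so the low share excludes nothing. Alleles near a Cre transgene were not tested.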
